A study of Mus musculus with 9 samples.

How the data were processed

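Gene expression was measured on Illumina mouse bead arrays in 9 samples of cultured mouse cells, 3 per culture, all hypoxic per the labels, at 1% O2 per the series' design text. NSC are cells of C17.2, a mouse neural stem cell line that the labels describe as immortalized with c-myc and carrying LacZ as a tracer, taken after 3 to 4 days of culture at 50% confluence. MMC are C17.2 cells whose differentiation was induced with mitomycin, a DNA-crosslinking drug, taken after 8 days. PNC are primary neurons of E17 mouse embryos of the C57BL/6J strain, taken after 8 days of culture, and the labels call the embryos most likely a mix of both sexes. The strain given for the line is C57BL/6J x CD1, and its sex is not known. RNA was extracted with the RNeasy kit from material the protocol calls frozen tissue, and 100 ng per sample was amplified and labelled with biotin, per the labels. No sample kept at normal oxygen is among the 9, so the response to hypoxia itself cannot be measured in any culture. A comparison of cultures also compares culture time, strain, and a cell line with primary cells. Confluence is given for NSC only, so cell density may differ as well.

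The main table holds the intensity of each of 45281 probes on each array on a linear scale, and BeadStudio is named for it, with no version, per the submitters' processing notes. The deposited intensity values were not background-subtracted or normalized, as their lowest values and differing quantiles show. A second deposited table holds the authors' processed intensity of the same arrays. The method behind it is not given in the sources used here. From the values, it is linear and not centred, its column medians lie between 65.4 and 66.0, and each column's rank correlation with the same array's unprocessed signals lies between 0.995 and 0.9999, so its direction is that of the unprocessed signals. It served as an alternative.

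The planned background correction needs detection p-values or control probes, and the tables hold neither. The background was therefore corrected with limma's normexp model (saddle-point fit, offset 16), and the arrays were quantile normalized on the log2 scale. A probe counted as above background on an array when its signal exceeded the mode of that array's signals by the upper 0.05 tail of a normal curve, with the standard deviation taken from the signals below the mode. Probes above background on at least 3 of the 9 arrays were kept, 29537 probes or 65.2%. Each gene was represented by its brightest probe over all arrays, which left 20319 genes, of which 6047 had more than 1 probe past the filter. Of all probes, 29586 were named by Entrez identifier and 2759 by transcript accession through a RefSeq table of assembly GRCm38.p6, used only for names and neighbours, and 12936 kept the symbol of the array's table, which can be old. Of the genes tested, 14566 were named through the reference. In 24 probes the symbol had been turned into a date, and these are not named.

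A linear model with 1 mean per culture was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg within each comparison. In the counts of genes per comparison a gene differs at an adjusted p under 0.05 and an absolute log2 difference of at least 1. In the counts within gene lists, and for single genes, a call is an adjusted p under 0.05 with no minimum difference. Values are log2 differences with the standard error (SE) of the fit over 3 arrays per culture, from two-sided tests. A moderated F test over both differences from NSC covers the whole design. Where no probe of a gene was above background on any array of a culture, the gene's fold difference is a bound, written "at least": the bright culture's mean is set against the dim culture's mean of, per array, the higher of the lowest normalized signal among probes above background and the probe's own signal. The log2 difference and SE printed beside such a bound are those of the fit, and rest on a dim culture at background. A fold without "at least" can still rest on a dim culture in which only 1 or 2 of the 3 arrays were above background. Folds are on the scale of the signal with its offset, which understates differences of dim genes. The 3 comparisons are PNC minus NSC, MMC minus NSC and PNC minus MMC.

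A total of 24 gene lists were fixed before the data were examined: pan-neuronal and cytoskeletal, presynaptic and vesicle, glutamatergic and postsynaptic, GABAergic, neuronal ion channels, neurogenic transcription factors, neural stem and progenitor, DNA replication and G1/S, mitosis and G2/M, p53 targets and DNA damage, senescence-associated secreted, HIF targets, glycolysis, oxidative phosphorylation, MYC targets and ribosome biogenesis, unfolded protein and amino acid stress, immediate early, interferon response, astrocyte, oligodendrocyte lineage, microglia and macrophage, endothelial and pericyte, fibroblast with extracellular matrix and contractile genes, and transforming growth factor beta and Wnt signalling. Some genes stand in more than one list, such as Aldoc, Sox9, Eno2, Lox and Sesn2. Each list was called with limma's camera at a preset correlation of 0.01 between genes, which compares a list with all other genes, with adjustment over the 24 lists within a comparison. Camera with a correlation estimated per list, and fry, which asks whether a list's genes move one way and compares them with no others, stand beside it.

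The genes named were also chosen by a rule fixed before the data were examined. Per comparison it takes the 5 largest differences in each direction among genes that passed the test and whose values do not overlap between cultures. Predicted or unnamed gene models are left out. Genes named only by the array's own symbol were also left out, which the rule as fixed did not state. The rule adds for each called list the pair of members that moved most in its direction and the one that moved most against it. It always adds Tubb3, Map2, Nes, Sox2, Gfap, Mki67, Cdkn1a, Vegfa and Myc. Members of near-identical gene families (Bglap, Prl2c, Lce, Tcstv, clustered histone genes) share sequence that a probe of 50 bases may not tell apart, so a value under 1 symbol is uncertain as to the copy.

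Simulated arrays with the NSC means and the fitted spreads of the 20319 genes, the same in all cultures, in which 200 genes per round were changed in the MMC minus NSC comparison over 10 rounds, tested the gene step. It called 35.5% of genes changed by 0.5 on the log2 scale, 99% of those changed by 1 and 100% of those changed by 2, and 5.49% of its calls were false. A list of 25 genes shifted by 0.5 was called in 10 of 10 rounds at an unadjusted camera p under 0.05, and an unshifted list in 1. The simulated genes were drawn independently. Within the real lists the estimated correlation runs from −0.060 (oligodendrocyte lineage) to 0.889 (DNA replication), with mitosis next to the highest at 0.360. Without NSC replicate 2 it is 0.046 for DNA replication and 0.366 for mitosis, so the value of 0.889 rests on that array. The simulated rounds thus do not show how the list step behaves with correlated genes. The number of arrays, 3 per culture, limits the precision. The sources used here do not say whether the 3 replicates of a culture were grown separately, so the p-values measure the spread between these samples, which may be technical.

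Alternatives were quantile normalization without background correction (50 added to each signal), scaling to a common median, the authors' processed values, an offset of 50, no filter and a stricter filter on dim probes (upper tail 0.01 on all arrays of at least 1 culture), all probes counted singly, an intensity trend with a robust prior, only the arrays of the cultures compared, array weights, no minimum difference, the replicate number as a block, and each array left out in turn. The BeadChip could not be used as a block, since the tables used here give no chip identifiers. A background set from the mode of each array was added after seeing the data, as was a look at the values without NSC replicate 2.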

Results

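At 1% O2 the primary neurons differ from both C17.2 cultures by a large share of all genes, while mitomycin-treated C17.2 cells (MMC) keep a profile close to that of untreated C17.2 cells (NSC). Correlations of log2 signal across genes run from 0.789 to 0.795 between NSC and PNC arrays, from 0.795 to 0.800 between MMC and PNC arrays, and from 0.974 to 0.978 between NSC and MMC arrays. Within cultures they run from 0.988 to 0.997. The first principal component, which separates PNC from the C17.2 cultures, holds 89.6% of the variance, the second 6.30% and the third 1.77%. The F test called 14662 of 20319 genes (72.2%) as differing among the 3 cultures. None of these values measures a response to hypoxia, since every sample was hypoxic. Whether the cultures respond to it differently cannot be told.

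The primary neuron cultures carry the transcripts of neurons at levels far above C17.2 cells. In PNC minus NSC, Stmn2, a microtubule regulator of growing axons, was at least 780-fold higher (log2 difference 9.99, SE 0.11, n = 3 per culture, adjusted p = 3.44e-15). Gap43, a growth cone protein, was at least 512-fold higher (9.49, SE 0.12). Fxyd6, a regulator of the sodium pump, was at least 705-fold higher (10.28, SE 0.14). Ttr, the thyroid hormone carrier made by the choroid plexus, was at least 825-fold higher (10.03, SE 0.11), and Ndn, which is expressed in postmitotic neurons, was 573-fold higher (9.16, SE 0.11) with 2 of the 3 NSC arrays above background. The largest differences the other way were those of Plac8 (−7.22, SE 0.13), the calcium-binding protein gene S100a4 (−7.12, SE 0.14), Angptl4, an inhibitor of lipoprotein lipase known as a HIF target (−7.08, SE 0.13), the surface antigen gene Ly6a (−6.93, SE 0.12) and the neurotrophic factor gene Gdnf (−6.79, SE 0.13). In all, 6652 genes differed by at least 2-fold, 3329 higher and 3323 lower in PNC, and 762 by at least 16-fold, 569 of them higher. The 3 values of each culture do not overlap for 14359 genes (70.7%), against 10% by chance, and the median difference over all genes is −0.11.

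The neuronal gene lists were higher in PNC as groups, by camera with the preset and with the estimated correlation. Of 21 pan-neuronal genes measured, 20 were higher and 0 lower than in NSC, with a list median of 5.90 (camera adjusted p = 3.61e-12, adjusted p = 0.00960 with an estimated correlation). Within lists, higher and lower are calls at an adjusted p under 0.05 with no minimum difference, and counts adjusted over the list alone are the same as over all genes here and below unless given. Presynaptic genes were higher for 19 of 22 (median 4.52, adjusted p = 1.36e-10, adjusted p = 0.00410 with an estimated correlation). Among them are the calcium sensor of vesicle release Syt1 (at least 253-fold) and the vesicle protein gene Syp (182-fold). Of 23 glutamatergic and postsynaptic genes 20 were higher (median 2.97, adjusted p = 2.66e-10, adjusted p = 0.00410 with an estimated correlation). The largest increases were those of the kinase gene Camk2b (138-fold) and the AMPA receptor gene Gria2 (about 109-fold, with 2 of the 3 NSC arrays above background). Of 15 GABAergic genes 13 were higher (median 2.65, adjusted p = 5.60e-07, adjusted p = 0.00834 with an estimated correlation). The neuropeptide gene Sst was at least 190-fold and the GABA synthesis gene Gad1 at least 178-fold higher. Ion channel genes were higher for 17 of 20, or 18 adjusted over the list alone (median 1.85, or 1.70 with genes at their bound, adjusted p = 1.83e-07, adjusted p = 0.00795 with an estimated correlation). The potassium channel gene Kcnd2 was at least 45.0-fold and the sodium pump subunit gene Atp1b1 55.1-fold higher.

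Neurogenic transcription factors were higher for 16 of 18 (median 3.21, or 2.87 with genes at their bound, adjusted p = 2.66e-09, adjusted p = 0.0247 with an estimated correlation). Myt1l, above background on 2 of the 3 NSC arrays, was about 173-fold and Bcl11a at least 105-fold higher. The neuron cultures also carry glial transcripts. Of 17 astrocyte genes 15 were higher in PNC and 1 lower (median 2.67, or 2.38 with genes at their bound, adjusted p = 3.59e-06, adjusted p = 0.0181 with an estimated correlation). The glutamate transporter gene Slc1a3 was 188-fold, the water channel gene Aqp4 26.7-fold and the filament gene Gfap 8.52-fold higher. In NSC, Slc1a3 and Aqp4 were above background on 1 of the 3 arrays and Gfap on 2, so these folds are approximate. The gap junction gene Gja1 was lower (−1.37, SE 0.098). Another probe of Aqp4 has the opposite sign. Map2, a dendritic microtubule protein gene, was 15.9-fold higher in PNC. Tubb3, whose probe is dim, rose by 0.98 (SE 0.19, adjusted p = 0.000573). The intermediate filament gene Nes, a progenitor marker, was lower (−2.67, SE 0.11). Sox2, a stem cell factor, differed by 0.26 (SE 0.13, adjusted p = 0.0862) and passes without NSC replicate 2 (0.37, adjusted p = 0.0108), without PNC replicate 1 (0.34, adjusted p = 0.0449) and with the authors' values (0.39, adjusted p = 0.00770). Probes of Snap25, Nefl and Gad2 lay below the filter and were not tested.

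Cell cycle genes were lower in the neurons. All 25 mitosis genes measured were lower in PNC than in NSC (median −2.50, camera adjusted p = 1.66e-10, adjusted p = 0.159 with an estimated correlation). Cdk1, a mitotic kinase gene, was at −4.03 (SE 0.20), the mitotic kinase gene Aurka at −3.11 (SE 0.11) and the proliferation marker Mki67 at −2.60 (SE 0.22). Of 29 DNA replication genes 27 were lower and 0 higher (median −1.78, adjusted p = 6.76e-06, adjusted p = 0.473 with an estimated correlation). The replication licensing gene Cdt1 was at −3.26 (SE 0.16) and the thymidine kinase gene Tk1 at −2.79 (SE 0.35). NSC replicate 2 stands apart from the other NSC arrays in this list, with a list median 1.23 above theirs. Without it the list median is −1.36 and the list passes also with an estimated correlation (adjusted p = 0.0352). MYC targets and ribosome biogenesis genes were lower for 18 of 25 and higher for 2 (median −0.85, adjusted p = 0.00120, adjusted p = 0.399 with an estimated correlation). Wdr43 was at −2.81 and Mybbp1a at −1.67, against Nme1 at 0.51 (adjusted p = 0.00429), a call that scaling to a common median ends (0.039, adjusted p = 0.814). Myc itself, on a dim probe, differed by −0.90 (SE 0.20, adjusted p = 0.00150). The line is immortalized with c-myc per the labels, and whether the probe sees that transgene was not tested.

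The HIF target list holds genes that the hypoxia-inducible factors are known to drive, and also the factor genes Hif1a, Epas1 and Hif3a. Its genes were lower in the hypoxic neurons than in hypoxic NSC for 20 of 28 and higher for 4 (median −0.89, camera adjusted p = 0.0113, adjusted p = 0.411 with an estimated correlation). The carbonic anhydrase gene Car9 was at −5.35 (SE 0.11, adjusted p = 2.06e-13) and Ero1a, an oxidase of protein folding, at least 8.47-fold lower. The mitochondrial gene Higd1a was 6.10-fold higher and the angiogenic factor gene Vegfa rose by 0.61 (SE 0.13, adjusted p = 0.00127). Another probe of Vegfa has the opposite sign. Unfolded protein and amino acid stress genes were lower for 18 of 26, or 20 adjusted over the list alone, and higher for 3 (median −0.82, adjusted p = 0.00356, adjusted p = 0.402 with an estimated correlation). Sdf2l1 was at −2.76, Trib3 at −2.75 and, the other way, the glutathione-degrading Chac1 at 1.14. Senescence-associated secreted genes were lower for 17 of 27 and higher for 6 (median −1.48, adjusted p = 0.00880, adjusted p = 0.330 with an estimated correlation). The list also holds the cell cycle inhibitor genes Cdkn2a and Cdkn2b, whose products are not secreted. Cdkn2a was at −6.08, with another probe of opposite sign, the protease gene Plau at −5.18, and Igfbp2 at least 59.8-fold higher. Fibroblast, matrix and contractile genes were lower for 21 of 30 and higher for 5 (median −2.53, adjusted p = 6.49e-05, adjusted p = 0.246 with an estimated correlation). The matricellular gene Ccn1 was at −5.47 and the matrix proteoglycan gene Bgn at 4.27.

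The lists of energy metabolism did not pass camera's test in PNC minus NSC. Of 17 glycolysis genes 4 were higher and 5 lower (median −0.11, mean 0.099, camera direction up, adjusted p = 0.994). Of 34 oxidative phosphorylation genes 12 were higher and 9 lower, or 8 lower adjusted over the list alone, and by at least 2-fold 1 was higher and 0 lower (median −0.0079, mean 0.087, adjusted p = 0.530), with a fry call of up (adjusted p = 0.0247) and a median of 0.041 without NSC replicate 2. The p53 target list, with 7 of 29 genes higher and 16 lower, or 17 lower over the list alone (median −0.45, adjusted p = 0.0751), passes without NSC replicate 2 (adjusted p = 0.0490, adjusted p = 0.428 with an estimated correlation), with no filter (0.0419) and by fry (5.26e-05). Cdkn1a, the p53-driven cell cycle inhibitor gene, differed by 0.048 (SE 0.11, adjusted p = 0.727), with another probe of opposite sign. Immediate early genes had 5 of 21 higher and 10 lower (median −0.37, adjusted p = 0.0644, adjusted p = 0.473 with an estimated correlation). This list passes without NSC replicate 2 (adjusted p = 0.0420, adjusted p = 0.395 with an estimated correlation), without PNC replicate 1 (median −0.83, adjusted p = 0.0296), with median scaling (0.0490), with no filter (0.0296) and by fry (3.53e-05). Neural stem and progenitor genes had 10 of 22 higher, or 11 over the list alone, and 8 lower (median 0.28, mean −0.0098, adjusted p = 0.798). Oligodendrocyte genes had 9 of 14 higher and 3 lower (median 0.98, or 0.75 with genes at their bound, adjusted p = 0.0751, called up by fry with adjusted p = 3.48e-08). Microglial genes had 7 of 16 higher and 5 lower (median 0.10, mean −0.16, camera direction up, adjusted p = 0.946). Endothelial genes had 1 of 12 higher and 5 lower (median −0.18, adjusted p = 0.0732, called down by fry with adjusted p = 4.77e-08). Interferon genes had 6 of 20 higher and 7 lower (median −0.075, adjusted p = 0.550, called down by fry with adjusted p = 2.92e-06). Transforming growth factor beta and Wnt genes had 8 of 23 higher and 10 lower, with a median of −0.26, a mean of 0.17, no camera call (direction down, adjusted p = 0.994) and a fry call of up (adjusted p = 0.000132).

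**Figure D1:**
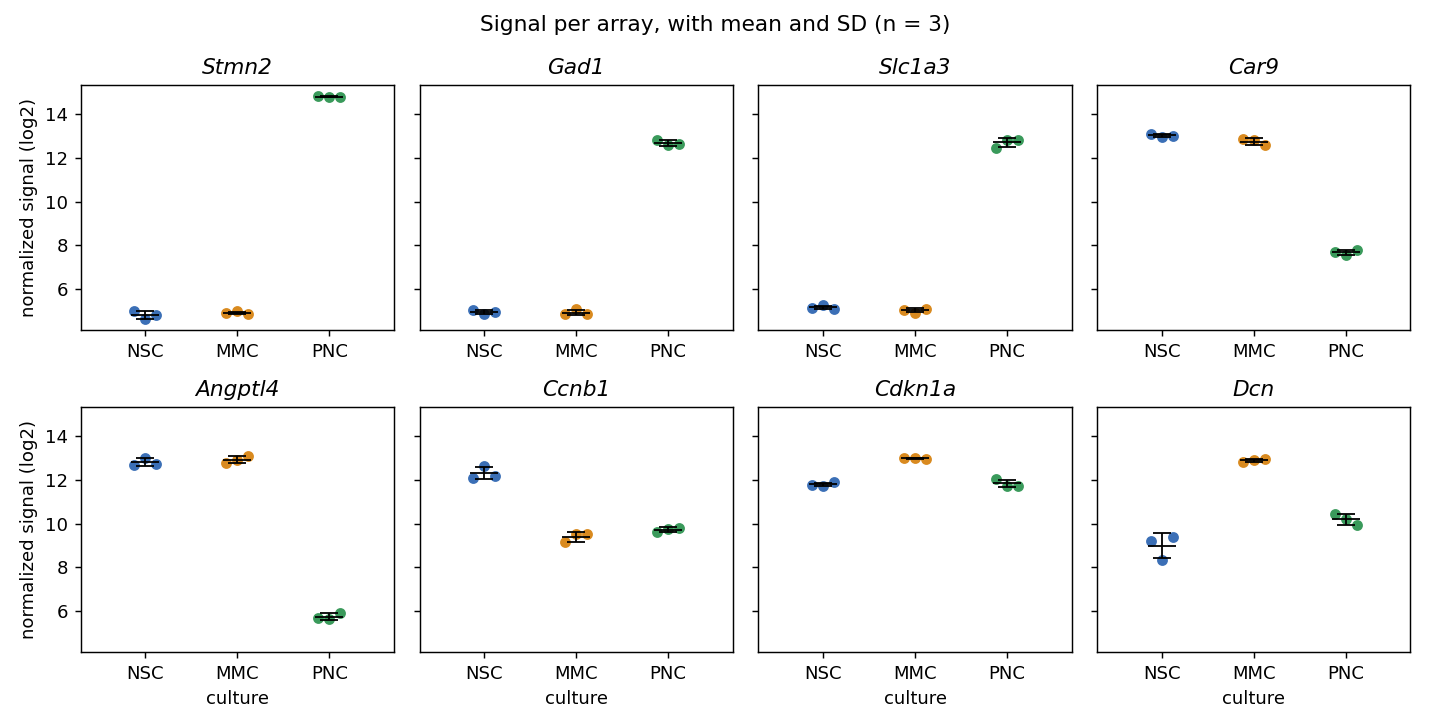
Normalized signal (log2) of 8 genes on each of the 9 arrays, with the mean and standard deviation of each culture (n = 3).

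**Figure D2:**
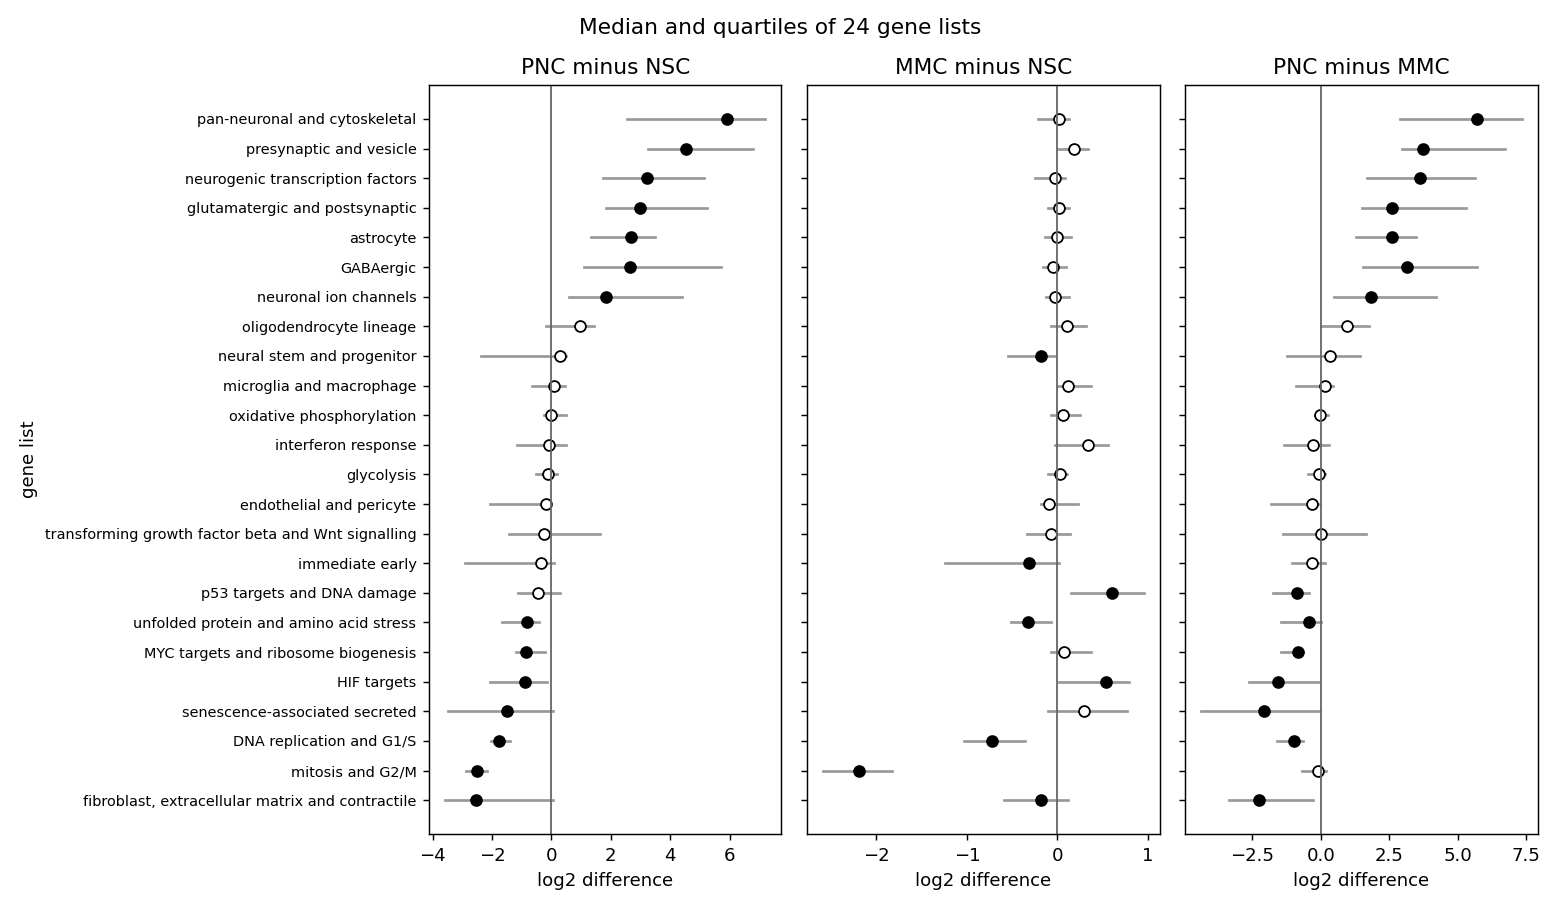
Median (points) and quartiles (lines) of the log2 differences of the 24 gene lists in each comparison; filled points mark lists with a camera adjusted p under 0.05.

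Mitomycin-treated C17.2 cells hold lower levels of the transcripts of dividing cells. In MMC minus NSC all 25 mitosis genes measured were lower, with a median of −2.19 (camera adjusted p = 1.94e-32, adjusted p = 0.115 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at −2.95 (SE 0.16, n = 3 per culture, adjusted p = 1.30e-07), the cyclin gene Ccnb1 at −2.91 (SE 0.15), the spindle gene Aspm 8.02-fold lower (SE 0.13 on the log2 scale) and Mki67 at −2.68 (SE 0.22). Of p53 targets and DNA damage genes, 19 of 29 were higher, or 20 adjusted over the list alone, and 2 lower, and by at least 2-fold 7 were higher and 0 lower (median 0.61, adjusted p = 6.65e-06, adjusted p = 0.306 with an estimated correlation). The p53 median is 0.48 without NSC replicate 2, with 17 higher and 3 lower, or 19 and 4 over the list alone (camera adjusted p = 0.000245, adjusted p = 0.339 with an estimated correlation). Cdkn1a was 2.31-fold (SE 0.11 on the log2 scale, adjusted p = 9.21e-06), the death receptor gene Fas 2.75-fold and the lesion-bypass polymerase gene Polk 2.38-fold higher, while Gtse1, a gene of G2 and S phase, was at −0.76. In all, 995 genes differed by at least 2-fold, 458 higher and 537 lower in MMC, and 0 by at least 16-fold. The count is 519 without background correction, 212 higher and 307 lower, and with no minimum difference 2908 are higher and 2560 lower. The values of the cultures do not overlap for 38.6% of genes, against 10% by chance, and the median difference over all genes is 0.0054.

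The genes that rose most in MMC have known roles in different tissues. Bglap2, a gene of the osteocalcin family, was 15.2-fold higher (SE 0.17 on the log2 scale, adjusted p = 3.08e-08), the matrix proteoglycan gene Dcn 15.0-fold (SE 0.22), Prl2c3, of the prolactin family, 11.6-fold (SE 0.20), Lce1g, of the late cornified envelope family, 10.9-fold (SE 0.23), and the synaptic vesicle gene Svop 9.75-fold (SE 0.21). The largest decreases, beside mitosis genes, were those of Tcstv3, at least 11.7-fold lower, the muscle troponin gene Tnnc2 (−3.47, SE 0.17) and the histone gene H3c3 (−3.02, SE 0.20), which was above background on 2 of the 3 MMC arrays. For Bglap2, Prl2c3, Lce1g, Tcstv3 and H3c3 the copy measured within the family is uncertain.

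Replication genes were lower in MMC for 13 of 29, or 15 adjusted over the list alone, with 0 higher (median −0.73, camera adjusted p = 3.91e-05, adjusted p = 0.597 with an estimated correlation, fry adjusted p = 0.128). The replication gene Gins1 (−1.48, SE 0.22) and the DNA ligase gene Lig1 (−1.41, SE 0.20) are among them. NSC replicate 2 has a list median 1.23 above the other NSC arrays, and without it the MMC median is −0.29, with 4 genes higher and 14 lower, or 5 and 15 over the list alone (adjusted p = 0.00808, adjusted p = 0.339 with an estimated correlation, fry adjusted p = 0.00141). HIF targets were higher in MMC for 13 of 28 and lower for 1, and by at least 2-fold 7 were higher and 0 lower (median 0.54, adjusted p = 0.00389, adjusted p = 0.580 with an estimated correlation). Ankrd37 was 3.18-fold, Higd1a 2.47-fold and Vegfa 1.53-fold higher. Without NSC replicate 2 the HIF median is 0.42 (adjusted p = 0.0149, adjusted p = 0.628 with an estimated correlation), with 12 higher and 1 lower, or 14 and 2 over the list alone. The 1 member the other way, Ero1a (−0.72, SE 0.25, adjusted p = 0.0471), loses its call when any array other than NSC replicate 2 is left out, with adjusted p from 0.0631 without PNC replicate 1 to 0.171 without NSC replicate 1. Progenitor genes were lower for 8 of 22 and higher for 1 (median −0.19, adjusted p = 0.00822, adjusted p = 0.508 with an estimated correlation). The inhibitors of differentiation Id3 (−1.52) and Id2 (−1.47) and Sox2 (−0.64, SE 0.13, adjusted p = 0.00223) were lower, and Nes rose by 0.54 (SE 0.11, adjusted p = 0.00234). Without NSC replicate 2 the progenitor median is −0.093 (adjusted p = 0.0343, adjusted p = 0.591 with an estimated correlation).

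Immediate early genes were lower in MMC for 8 of 21 and higher for 4 (median −0.31, camera adjusted p = 0.0144, adjusted p = 0.580 with an estimated correlation). The activity-induced factor gene Egr3 was at −2.73, its relative Egr4 at −2.56 and Ier3 at 1.07. Within the unfolded protein and amino acid stress list 10 of 26 were lower, or 13 over the list alone, and 3 higher (median −0.33, adjusted p = 0.0209, adjusted p = 0.580 with an estimated correlation, fry adjusted p = 0.116). The chaperone gene Hspa5 (−1.38, SE 0.18) and its regulator Xbp1 (−0.96, SE 0.19) were lower, while the stress factor gene Ddit3 was 4.48-fold higher. The list loses its call without NSC replicate 1 (adjusted p = 0.0631), NSC replicate 3 (0.0624) or MMC replicate 3 (0.0510), while without NSC replicate 2 it has 14 lower and 3 higher, or 15 and 3 over the list alone (adjusted p = 0.00293, adjusted p = 0.494 with an estimated correlation, fry adjusted p = 0.00507). Fibroblast, matrix and contractile genes were lower for 11 of 30 and higher for 4 (median −0.18, adjusted p = 0.0489, adjusted p = 0.597 with an estimated correlation). The matricellular gene Thbs1 was at −2.14 and the collagen gene Col3a1 at −1.46, against Dcn, which was higher. This call is lost without NSC replicate 1 (adjusted p = 0.0631), NSC replicate 2 (0.109) or MMC replicate 2 (0.0799) and without background correction (0.0541). Myc differed by −0.59 (SE 0.20, adjusted p = 0.0489) and loses its call when any array other than NSC replicate 2 is left out, with adjusted p from 0.0602 without MMC replicate 3 to 0.186 without MMC replicate 2.

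None of the neuronal lists passed camera's test in MMC minus NSC. Under other settings the presynaptic list is called up, and the GABAergic list is called down by fry (adjusted p = 0.00434). Pan-neuronal genes had 3 of 21 higher and 2 lower (median 0.019, mean 0.036, camera direction down, adjusted p = 0.976), or 3 and 4 without NSC replicate 2 (median −0.0025), with Map2 lower (−1.26, SE 0.12, adjusted p = 7.09e-06) and Tubb3 at 0.11 (SE 0.19, adjusted p = 0.737). Presynaptic genes had 5 of 22 higher, or 7 over the list alone, and 2 lower (median 0.18, adjusted p = 0.0591, adjusted p = 0.306 with an estimated correlation), and pass without MMC replicate 2 (adjusted p = 0.0482), with median scaling (0.0448), with no filter (0.0221) and by fry (5.61e-05). Glutamatergic genes had 2 of 23 higher and 0 lower (median 0.019, adjusted p = 0.858), and without NSC replicate 2 they had 2 higher and 3 lower, or 0 lower over the list alone (median −0.015). GABAergic genes had 0 of 15 higher and 3 lower (median −0.043, adjusted p = 0.364). Ion channel genes had 2 of 20 higher and 1 lower (median −0.030, adjusted p = 0.976). Neurogenic factors had 2 of 18 higher and 2 lower (median −0.027, adjusted p = 0.694), or 2 and 3 without NSC replicate 2 (median −0.094). Glial lists did not pass camera's test either: astrocyte genes had 3 of 17 higher and 1 lower (median −0.0020, mean 0.084, camera direction up, adjusted p = 0.858), with Gfap at 0.15 (SE 0.14, adjusted p = 0.482). Oligodendrocyte genes had 3 of 14 higher, or 2 over the list alone, and 0 lower (median 0.11, adjusted p = 0.364), and are called up by fry (adjusted p = 0.00225).

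Of the remaining lists in MMC minus NSC, senescence-associated secreted genes had 10 of 27 higher, or 12 over the list alone, and 4 lower (median 0.30, adjusted p = 0.0669, adjusted p = 0.580 with an estimated correlation), and pass without MMC replicate 1 (adjusted p = 0.0420), without PNC replicate 1 (0.0358), with no filter (0.0176) and by fry (0.0486). Interferon genes had 9 of 20 higher, or 11 over the list alone, and 3 lower (median 0.34, adjusted p = 0.0618, adjusted p = 0.306 with an estimated correlation), and pass without NSC replicate 2 (adjusted p = 0.0471, adjusted p = 0.339 with an estimated correlation), without MMC replicate 2 (0.0475), with median scaling (0.0448) and by fry (0.00225). Microglial genes had 4 of 16 higher and 1 lower (median 0.12, adjusted p = 0.119), and are called up by fry (adjusted p = 0.0164). Endothelial genes had 2 of 12 higher and 2 lower (median −0.092, mean 0.0013, adjusted p = 0.976), or 3 and 1 without NSC replicate 2. Transforming growth factor beta and Wnt genes had 2 of 23 higher and 5 lower, or 3 and 6 over the list alone (median −0.068, adjusted p = 0.364), and 4 higher and 6 lower without NSC replicate 2. MYC targets had 5 of 25 higher and 2 lower (median 0.074, adjusted p = 0.366), and without NSC replicate 2 they had 10 higher and 2 lower (median 0.19, adjusted p = 0.0572, fry adjusted p = 0.0445). Oxidative phosphorylation genes had 4 of 34 higher and 0 lower (median 0.061, adjusted p = 0.372), and without NSC replicate 2 they had 9 higher and 2 lower (adjusted p = 0.348, fry adjusted p = 0.0442). Glycolysis genes had 3 of 17 higher and 1 lower (median 0.032, adjusted p = 0.976), or 2 and 1 without NSC replicate 2 (median −0.044). With an estimated correlation 0 of the 24 lists pass in this comparison, against 8 with the preset one.

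**Figure D3:**
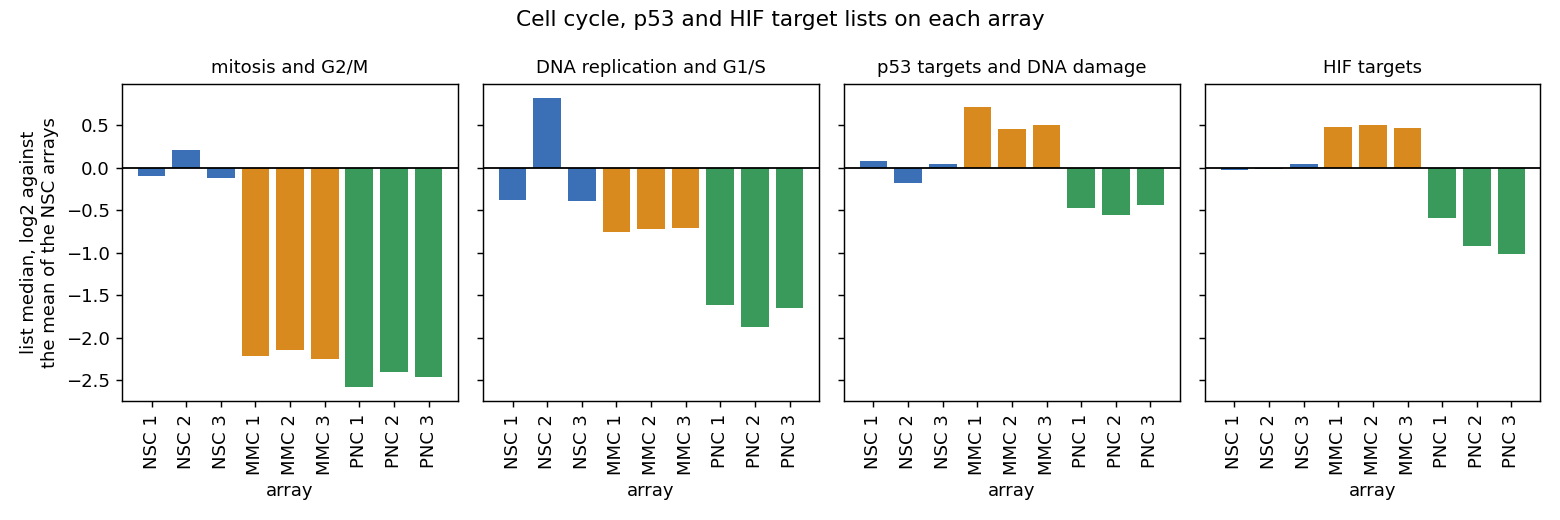
List medians of the log2 difference from the mean of the NSC arrays, on each array, for the mitosis, DNA replication, p53 target and HIF target lists.

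Set against MMC, which were cultured for the same 8 days, the neuron cultures again hold far more of the transcripts of neurons. The largest differences also include the choroid plexus gene Ttr and the oligodendrocyte lineage gene Olig1. In PNC minus MMC, Ttr was at least 818-fold, Stmn2 at least 774-fold, Fxyd6 at least 699-fold and Gap43, above background on 1 of the 3 MMC arrays, about 568-fold higher, and Olig1, a factor of the oligodendrocyte lineage, at least 395-fold (log2 difference 9.06, SE 0.13, n = 3 per culture). The cornified envelope gene Lce1g was at least 127-fold lower in PNC, and the interferon-inducible Ifi202b (−7.31, SE 0.15, above background on 2 of the 3 PNC arrays), Plac8 (−7.25, SE 0.13), Angptl4 (−7.20, SE 0.13) and the membrane glycoprotein gene Gpnmb (−7.20, SE 0.13) followed. In all, 6454 genes differed by at least 2-fold, 3237 higher and 3217 lower in PNC, and 748 by at least 16-fold, 555 of them higher. The values do not overlap for 71.5% of genes, against 10% by chance, and the median difference over all genes is −0.11.

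Pan-neuronal genes were higher in PNC than in MMC for 19 of 21 and lower for 0 (median 5.69, camera adjusted p = 6.61e-12, adjusted p = 0.0101 with an estimated correlation). Map2 was 38.2-fold higher and Tubb3 at 0.87 (SE 0.19, adjusted p = 0.00148). Presynaptic genes were higher for 19 of 22 and lower for 2 (median 3.74, adjusted p = 5.24e-10, adjusted p = 0.00440 with an estimated correlation). Syt1 was at least 251-fold and the vesicle release gene Cplx1 at least 218-fold higher and the active zone gene Bsn at −1.47, with 2 of the 3 PNC arrays above background. Glutamatergic genes were higher for 20 of 23 and lower for 0, or 1 over the list alone (median 2.60, adjusted p = 3.79e-10, adjusted p = 0.00440 with an estimated correlation). Camk2b (132-fold) and the postsynaptic scaffold gene Dlgap1 (122-fold) lead it. GABAergic genes were higher for 13 of 15 and lower for 1 (median 3.17, adjusted p = 7.40e-08, adjusted p = 0.00654 with an estimated correlation). Sst was at least 188-fold and Gad1 at least 177-fold higher.

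Ion channel genes were higher in PNC than in MMC for 17 of 20 and lower for 0 (median 1.83, or 1.63 with genes at their bound, camera adjusted p = 3.13e-07, adjusted p = 0.00654 with an estimated correlation). Atp1b1 was 126-fold and Kcnd2 at least 44.7-fold higher. Neurogenic factors were higher for 16 of 18 and lower for 0 (median 3.61, or 3.26 with genes at their bound, adjusted p = 2.30e-09, adjusted p = 0.0237 with an estimated correlation). Myt1l was about 222-fold and Bcl11a about 106-fold higher, each above background on 1 of the 3 MMC arrays. Astrocyte genes were higher for 15 of 17 and lower for 2 (median 2.59, or 2.36 with genes at their bound, adjusted p = 6.31e-06, adjusted p = 0.0196 with an estimated correlation). Slc1a3 was at least 181-fold, Aqp4 at least 20.8-fold and Gfap, above background on 2 of the 3 MMC arrays, about 7.68-fold higher and the calcium-binding protein gene S100b at least 4.88-fold lower. Nes was lower (−3.22, SE 0.11) and Sox2 rose by 0.89 (SE 0.13, adjusted p = 2.93e-05).

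The p53 target, HIF target, senescence-associated and matrix lists were lower in PNC than in MMC by camera with the preset correlation. Of p53 targets 22 of 29 were lower and 4 higher (median −0.87, camera adjusted p = 0.000266, adjusted p = 0.237 with an estimated correlation). The growth arrest gene Gadd45a was at −4.16 (SE 0.16), Phlda3 at −3.10 and Cdkn1a at −1.16 (adjusted p = 9.00e-07), and the cell death gene Bbc3 3.36-fold higher. HIF targets were lower for 20 of 28 and higher for 3 (median −1.57, adjusted p = 0.000662, adjusted p = 0.252 with an estimated correlation). Car9 was at −5.07 (SE 0.11), the oxygen-sensing hydroxylase gene Egln3 at −3.65 (SE 0.19), Higd1a 2.47-fold higher and Vegfa at 0.0033 (SE 0.13, adjusted p = 0.985, with another probe of opposite sign). Senescence-associated secreted genes were lower for 19 of 27 and higher for 6 (median −2.07, adjusted p = 0.00329, adjusted p = 0.237 with an estimated correlation). Plau was at −6.36, the chemokine gene Cxcl1 at −6.30 and Igfbp2 at least 59.3-fold higher. Fibroblast, matrix and contractile genes were lower for 22 of 30 and higher for 6 (median −2.27, adjusted p = 0.000123, adjusted p = 0.237 with an estimated correlation). S100a4 was at −6.18, the smooth muscle actin gene Acta2 at −5.75 and Bgn 27.4-fold higher.

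MYC targets were lower in PNC than in MMC for 21 of 25 and higher for 1 (median −0.84, camera adjusted p = 0.000262, adjusted p = 0.272 with an estimated correlation). Wdr43 was at −2.29, the pyrimidine synthesis gene Cad at −2.06 and Nolc1 at 0.57. Myc itself was at −0.31 (adjusted p = 0.192), and passes without NSC replicate 2 (adjusted p = 0.0327). Replication genes were lower for 22 of 29, or 23 over the list alone, and higher for 1 (median −0.99, adjusted p = 0.00551, adjusted p = 0.674 with an estimated correlation), and without NSC replicate 2 lower for 24 and higher for 5 (adjusted p = 0.000130, adjusted p = 0.0845 with an estimated correlation). Cdc45 was at −2.91 and Cdt1 at −2.44. The 1 higher, Gins1 (0.54, adjusted p = 0.0485), loses its call without any 1 of the MMC arrays or PNC replicates 2 and 3, with adjusted p from 0.0693 without MMC replicate 2 to 0.161 without MMC replicate 1. Unfolded protein and amino acid stress genes were lower for 15 of 26 and higher for 4 (median −0.41, adjusted p = 0.0283, adjusted p = 0.525 with an estimated correlation, and adjusted p = 0.0691 with the authors' values). Ddit3 was at −2.98, Trib3 at −2.83 and the disulfide isomerase gene Pdia6 at 0.91. Mitosis genes, lower than in NSC in both cultures, had 3 of 25 higher and 9 lower, or 1 and 8 over the list alone (median −0.084, adjusted p = 0.393, called down by fry with adjusted p = 0.0207), and 6 higher and 11 lower without NSC replicate 2. Mki67 was at 0.085 (SE 0.22, adjusted p = 0.749, with another probe of opposite sign).

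The lists that did not pass camera's test in PNC minus MMC include those of energy metabolism: glycolysis genes had 3 of 17 higher and 6 lower (median −0.065, mean 0.032, camera direction down, adjusted p = 0.901). Oxidative phosphorylation genes had 9 of 34 higher and 7 lower, or 7 and 4 over the list alone (median −0.015, mean 0.012, adjusted p = 0.698). Progenitor genes had 13 of 22 higher and 7 lower (median 0.34, or 0.32 with genes at their bound, adjusted p = 0.280, called up by fry with adjusted p = 0.00541). Immediate early genes had 5 of 21 higher and 10 lower (median −0.32, adjusted p = 0.280, called down by fry with adjusted p = 0.000854). Interferon genes had 3 of 20 higher and 10 lower (median −0.27, adjusted p = 0.124, called down by fry with adjusted p = 6.06e-07). Oligodendrocyte genes had 8 of 14 higher and 3 lower (median 0.98, or 0.77 with genes at their bound, adjusted p = 0.0896, called up by fry with adjusted p = 9.50e-08). Endothelial genes had 1 of 12 higher and 7 lower (median −0.32, adjusted p = 0.0896, called down by fry with adjusted p = 4.28e-08). Microglial genes had 6 of 16 higher and 6 lower (median 0.14, mean −0.45, camera direction down, adjusted p = 0.923, called down by fry with adjusted p = 0.000716). Transforming growth factor beta and Wnt genes had 9 of 23 higher and 10 lower (median 0.026, adjusted p = 0.599, called up by fry with adjusted p = 3.39e-05).

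Genes lower in MMC than in NSC are to a large extent genes that are also lower in PNC than in NSC. Of the 537 genes lower by at least 2-fold in MMC, 372 (69.3%) were also lower in PNC, where independent calls would give 87.8, and mitosis genes such as Cdc20, Ccnb1 and Aspm are among those lower in MMC. Of the 458 genes higher in MMC, 132 (28.8%) were also higher in PNC, with 75.04 for independent calls. The opposite pairs hold 101 genes lower in PNC and higher in MMC (74.9 for independent calls) and 50 genes higher in PNC and lower in MMC (88.0). Across the 20319 genes, which are not independent replicates, the MMC and PNC differences from NSC correlate with r = 0.188 (Spearman 0.228), and 58.9% have the same sign. The same 3 NSC arrays stand in both differences and cannot be split, and arrays simulated with no difference between cultures give r from 0.485 to 0.511 in 100 rounds, with a mean of 0.499, and the same sign in 66.7%. The simulated arrays hold no real differences, so their r and share of equal signs follow from the shared NSC arrays alone. They are no yardstick for the observed values. Independent calls in turn ignore the shared arrays, and no overlap of calls was simulated. Part of the overlap may come from the shared arrays, and how much is not known. The covariance of the differences is 0.140, against 0.0102 simulated from the shared arrays, which leaves 0.130. The simulation gave each gene the same spread in all cultures. The median absolute log2 difference between arrays of a culture reaches 0.225 in NSC, 0.156 in MMC and 0.145 in PNC. The value of 0.0102 may thus understate the part of the shared NSC arrays. Along the line from the NSC mean to the PNC mean, each mean taken without the array that is placed, MMC arrays lie at 5.20% to 6.01%, NSC arrays at 0.0746%, 3.09% (replicate 2) and 0.178%, and PNC arrays at 98.9% to 99.8%.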

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

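The replicate numbers served as a block in the same fit, which left 6653, 995 and 6455 genes in PNC minus NSC, MMC minus NSC and PNC minus MMC, 14601 genes in the F test, a correlation of 0.188 and 14, 8 and 14 lists. Arrays of the same number in different cultures share only a number: of 9 such pairs, with residual correlations from −0.030 to 0.112, 1 exceeds 0.1, and 3 arrays correlate best with their own number. The block changed no call of a list or of a named gene, and under it the camera direction of glycolysis in PNC minus NSC (median −0.11) and of ion channels in MMC minus NSC (median −0.030) turned, neither called. A BeadChip block was not run, since the tables used here give no chip. The background from the mode of each array, and the separate look at the values without NSC replicate 2, were chosen after seeing the data.

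Most counts kept within 1.5 times. Those that did not, in the order of the comparisons above, are the 13516, 5468 and 13136 genes without a minimum difference, which is by construction, and the 519 genes of MMC minus NSC under quantile normalization without background correction. Lists called number 7, 0 and 7 with an estimated correlation, and 22 in PNC minus MMC with fry. The correlation of the MMC and PNC differences is 0.209 with array weights. Leaving out 1 array at a time gave 6623 to 6790, 992 to 1101 and 6388 to 6496 genes, 13664 to 15458 in the F test, correlations from 0.182 to 0.214 (the highest without NSC replicate 2), and 14 to 16, 6 to 9 and 14 to 14 lists. For the alternatives, counts were 6723, 1032 and 6469 with median scaling, 5754, 766 and 5456 with the authors' values, and 7197, 1209 and 6982 with the background from the mode. Over all settings 32 list results lost a call and 35 gained one, as did 41 and 4 of the named gene results. Fry called 21, 12 and 22 lists. For all but the size threshold the cause was not tested.

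Directions turned only where nothing was called, except for transforming growth factor beta and Wnt genes in PNC minus NSC, called up by fry (median −0.26). With fry the direction also turned for progenitor (0.28) and microglial genes (0.10) in PNC minus NSC, ion channel (−0.030), glycolysis (0.032) and endothelial genes (−0.092) in MMC minus NSC, and glycolysis in PNC minus MMC (−0.065). Without background correction it turned in PNC minus NSC for glycolysis (−0.064) and transforming growth factor beta and Wnt genes (−0.22), and in MMC minus NSC for ion channels (−0.010), glycolysis (0.012) and endothelial genes (−0.028). With median scaling it turned for Cdkn1a (−0.13), glycolysis (−0.40), oxidative phosphorylation (−0.18) and transforming growth factor beta and Wnt genes (−0.41) in PNC minus NSC, for ion channels (−0.032) and endothelial genes (−0.085) in MMC minus NSC, and for Vegfa (−0.26) and oxidative phosphorylation (−0.17) in PNC minus MMC. The authors' values turned glycolysis (−0.045) and microglial genes (0.079) in PNC minus NSC and endothelial genes (−0.048) in MMC minus NSC. No filter turned ion channels (−0.013) and endothelial genes (0.061) in MMC minus NSC, and the background from the mode turned transforming growth factor beta and Wnt genes in PNC minus NSC (−0.27) and ion channels in MMC minus NSC (−0.022).

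Leaving out 1 array turned the direction within these ranges, none called: in PNC minus NSC, Cdkn1a from −0.054 to 0.099, glycolysis from −0.15 to −0.085 and transforming growth factor beta and Wnt genes from −0.40 to −0.21. In MMC minus NSC they are Tubb3 from −0.11 to 0.29, pan-neuronal genes from −0.053 to 0.040, ion channels from −0.037 to −0.0063, glycolysis from −0.044 to 0.075 and endothelial genes from −0.12 to −0.019. In PNC minus MMC they are Vegfa from −0.059 to 0.072 and microglial genes from 0.093 to 0.18. The list values are medians, and a turn of camera's direction need not turn the median.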

Other observations

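Several genes known from early cleavage embryos were lower in both other cultures than in NSC, with no test of the group. Of 20 such genes, a list chosen after 3 of its members had been seen, 8 were measured, and 6 were lower and 0 higher in MMC than in NSC (median −1.15). They include Tcstv3, Tcstv1, at least 5.34-fold lower, Zscan4c, at least 4.59-fold lower, and Zfp352, at least 1.62-fold lower. In PNC minus NSC 7 were lower and 1 higher (median −1.12). Of 54 clustered histone genes, whose near-identical copies a probe may not tell apart, 28 were lower and 4 higher in MMC than in NSC (median −0.39), and 41 were lower and 0 higher in PNC than in NSC (median −1.05). In PNC minus MMC 33 were lower and 9 higher. NSC replicate 2, which stands apart in DNA replication genes, is part of both comparisons with NSC. No histone values without it are given here, so its share in these decreases is not known. The histone genes, too, were chosen after the values were seen.

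Xist, transcribed from the inactive X chromosome, was about 43.1-fold higher in PNC than in NSC (adjusted p = 6.40e-13), where 1 of the 3 arrays was above background. Its mean log2 signal was 5.13 in NSC, 5.06 in MMC and 10.55 in PNC. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were above background on all arrays of all 3 cultures, so C17.2 cells hold Y-linked transcripts. In PNC minus NSC these genes were lower: Ddx3y at −0.35 (adjusted p = 0.0197), Eif2s3y at −1.04 and Kdm5d at −1.05. Of 33 probes with a number in place of a gene name, 13 were above background on all C17.2 arrays, and 4 were lower by at least 16-fold in PNC. What they measure is not given in the sources used here.

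The counts of genes were set against other groupings of the arrays, as planned before the values were seen. For each pair of cultures 1 of the 10 splits of 6 arrays, the real one, gives a count as large as the real 6652, 995 or 6454, and the highest other count is 0. So few splits cannot give a share under 0.05. For the F test 1 of 100 drawn splits of the 9 arrays, the real one, reaches 14662, and the highest other count is 10948.

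NSC replicate 2 stands apart in DNA replication genes, a pattern seen in the data, and the tests of probe GC content and of a wrong label were chosen only after the result was seen. All 29 replication genes were above both other NSC arrays (median 1.23, quartiles 0.88 to 1.40), while NSC replicates 1 and 3 differ by 0.053, and 254 genes were more than 2-fold higher and 172 lower, against 3 between replicates 1 and 3. With a trend on probe GC content taken out the median is 1.22, so GC content could account for little of it. A mislabelled MMC array is not a possible source by the mitosis list, whose median is 0.32 above the other NSC arrays, where MMC lies at −2.19. A larger share of cells in S phase stays possible but undecided. The 20 further S-phase genes, a test written before its value was seen, were all above both other arrays (median 1.11). They belong to the same phase as the replication list, so they cannot tell more cells in S phase from higher levels per cell.

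Some genes of the epidermal differentiation region, from S100a1 to S100a10, were higher in MMC than in NSC, and the region was chosen only after Lce1g, Kprp, S100a8, Crct1 and Ivl had been seen among the largest differences, so its share of such genes is no test, though both tests below were written before their values. Of 38 of its 70 genes tested, 14 were higher and 4 lower, S100a3, S100a4 (−0.94), S100a1 (−0.75) and Tdpoz8 (−0.52), and 8 were at least 2-fold higher (21.1%, against 2.22% of genes elsewhere) and 1 at least 2-fold lower, S100a3. After Lce1g they are Kprp (7.28-fold), S100a8 (5.01-fold), Crct1 (4.91-fold), Ivl (at least 3.14-fold), Sprr2h (2.54-fold), Sprr1a (2.50-fold) and Lce3c (2.38-fold). Cross-hybridizing copies stay open: 7 of the 8 have a probe that shares no 20 bases with a probe of another gene of the region, but transcripts were not searched, as no sequences of them were at hand. The 11 keratinocyte markers measured outside the region were not higher as a set (median −0.010, quartiles −0.16 to 0.40). Of these, 2 were called higher, Col17a1 (0.76) and Itgb4 (0.70), and 1 lower, Krt14 (−0.76). This argues only against keratinocytes that carry these markers, and no biological explanation was tested.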
